A study of Glycine max with 27 samples.

How the data were processed

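Gene expression was measured with the Affymetrix Soybean Genome array in root tips of soybean (Glycine max) cultivar Magellan. Seedlings grew in a mixture at a water potential of -0.1 MPa (well-watered) or -1.6 MPa (water-stressed). Root tips were divided into regions 1 and 2 for stressed roots and regions 1 to 3 for well-watered roots, collected after 5 h or 48 h, and region 3 has arrays at 48 h alone. This gave 9 groups with 3 arrays each, 27 arrays in all, 1 biotin-labelled sample per array. The labels describe the replicates as biological and give about 300 roots for each sample. The labels do not say how far from the tip each region lies. They name a standard biotin labelling of cRNA and also a whole-transcript kit, and which of them was used is not given in the sources used here.

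The deposited values are intensities on a linear scale, scaled or normalized by the authors, per the labels with MAS5, whose version and settings are not given in the sources used here. They run from 4.11 to 59914.78. The upper quartile of all probe sets lies between 344.6 and 404.3 on every array, and 3.57% of the values are shared exactly between arrays of 1 probe set, so the values were taken as already normalized between arrays. No further scaling was applied in the fit reported first, and the values were put on the log2 scale without a pseudocount. The raw scans were not used here, so neither the summary of probes to probe sets nor its background correction was repeated.

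Of the 61170 probe sets on the array, 37593 belong to soybean, 15820 to Phytophthora sojae, 7530 to Heterodera glycines and 227 are controls. The background level of an array is the 95th percentile of the probe sets made for the other species. It lay between 49.64 and 71.01. A soybean probe set was tested when it exceeded the background level on at least 3 arrays, which left 29884. The platform annotation ties 8677 soybean probe sets to a single gene, 370 to several and 28546 to none, so most called probe sets carry no gene name. Symbols come from that annotation, and 1005 genes carry a symbol that is a name. The gene table of a RefSeq annotation held the identifiers of 8652 of these probe sets and changed 0 symbols. Where a gene has several tested probe sets, the one with the highest mean stands for it.

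Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with a mean for each group was fitted to all 27 arrays, with an intensity trend in the moderation of variances (18 residual and 3.26 prior degrees of freedom). The p values, from two-sided tests, were adjusted by the Benjamini-Hochberg method over the 29884 probe sets within each comparison, and a probe set is called at an adjusted p under 0.05. The 16 comparisons are stress within each region and time (4), stressed region 2 against well-watered region 3 at 48 h, regions within treatment and time (5), the times within well-watered regions (2) and the differences between stress effects (4). A gene whose lower group lies below background on all 3 arrays is given as a lower bound on its fold difference, taken against the background level. With 1 or 2 of those arrays above background the difference is given as measured, and its size is less certain.

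The named genes follow a rule fixed before the data were examined, except that it asked for a described gene and the annotation gives no descriptions, so a symbol that is a name was asked for instead. Among called genes with a named symbol, groups that do not overlap and a higher group above background on all 3 arrays, the 8 largest rises and 8 largest falls were taken for the 5 comparisons of stressed with well-watered roots and 5 of each for the others. For each gene list with a called member or a called set test, the 2 members (1 in the other comparisons) of smallest adjusted p were added. The text gives a part of these genes. Separation of groups was not asked of the differences between stress effects. In comparisons that hold either of the 2 arrays lying apart from their groups, the rule was applied again to 25 arrays, which was chosen after the data were seen.

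Gene lists were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the residuals, over the 30 lists with at least 5 tested genes, adjusted within each comparison. Because the annotation carries symbols without descriptions, most lists fixed before the data were examined matched too few genes, and 9 of the 30 are of that kind. The others were written from the symbols once the annotation and summaries of the values had been seen and before any comparison was made. The planned list of auxin response and transport also matched unrelated symbols and was left out.

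The fit was tested on simulated data for the first comparison, with the residual spread of each probe set. Of 50 simulated probe sets each, 14% were recovered at a fold of 1.5, 48% at 2, 86% at 4 and 98% at 8. Among 129 calls 6 were of unchanged probe sets. The list test called 1 list in 10 runs without a shift, and it called a list of 32 genes shifted by 0.5 log2 in 10 of 10. The noise was drawn independently for each probe set, so these runs cannot show how the list test behaves when genes are correlated. Every group of a probe set was given the same spread, estimated with the 2 arrays lying apart from their groups. These rates therefore need not hold for the real comparison, whose groups differ in spread.

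Alternatives covered quantile normalization, median centring, the background level added before the logarithm, no filter and a stricter one, no intensity trend, the replicate number as a factor, array weights, an adjusted p under 0.01, a fit on the compared groups alone and the omission of each array. Other splits of the arrays into groups of the same sizes were also tested. For the differences between stress effects, values below the background level of an array were also raised to it, which was chosen after the data were seen. Arrays with the same replicate number deviated together from their group means, with all 3 correlations over 0.1, in 3 of the comparisons. These were stressed regions 1 and 2 at 5 h (0.23, 0.56 and 0.62), well-watered regions 1 and 2 at 48 h (0.44, 0.40 and 0.42) and well-watered region 2 between the times (0.18, 0.22 and 0.20). The rule was also met by well-watered region 1 at 48 h with region 2 at 5 h (0.21, 0.23 and 0.34), which no comparison joins. Sections cut at different times come from different roots, so agreement by number need not mean shared roots. The pairing by number comes from the data, since the labels do not say that the sections of a number came from the same roots. The labels give no batch or hybridisation day, so none was modelled. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.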

Results

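Expression was measured in the growing tip of the soybean (Glycine max) primary root, cultivar Magellan, in seedlings kept well watered at a water potential of -0.1 MPa or stressed at -1.6 MPa. The tips were cut into numbered regions. Region 1 and region 2 were collected after 5 h and 48 h from both treatments, and region 3 was collected after 48 h from well-watered roots. Each of the 9 groups had 3 arrays described as biological replicates, and each sample pooled about 300 roots. On each of the 27 arrays between 66.8% and 77.2% of the soybean probe sets lay above the background level, which ran from 49.6 to 71.0 intensity units. The number of arrays limits the precision of every value. No genome build came with the values, so genes are given by symbol without coordinates. Differences are on the log2 scale with a standard error (SE), which rests on a spread shared by all groups.

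On 22 of the 27 arrays the nearest array belonged to the same group. The array labelled water-stressed region 2 at 48 h, replicate 3, lay nearest to a well-watered region 2 array of that time. The array labelled well-watered region 3 at 48 h, replicate 1, lay nearest to a water-stressed region 2 array. Both stayed in the groups their labels give. Of the other 3, 2 lay nearest to these arrays (well-watered region 2, replicate 3, and water-stressed region 2, replicate 1, both of 48 h). Replicate 1 of water-stressed region 1 at 5 h lay nearest to an array of that treatment and region at 48 h. The number of probe sets called in each comparison is followed by the number from the other 25 arrays, an alternative chosen after the data were seen, while gene lists are given with 27 arrays unless the 25 are named.

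**Figure D1:**
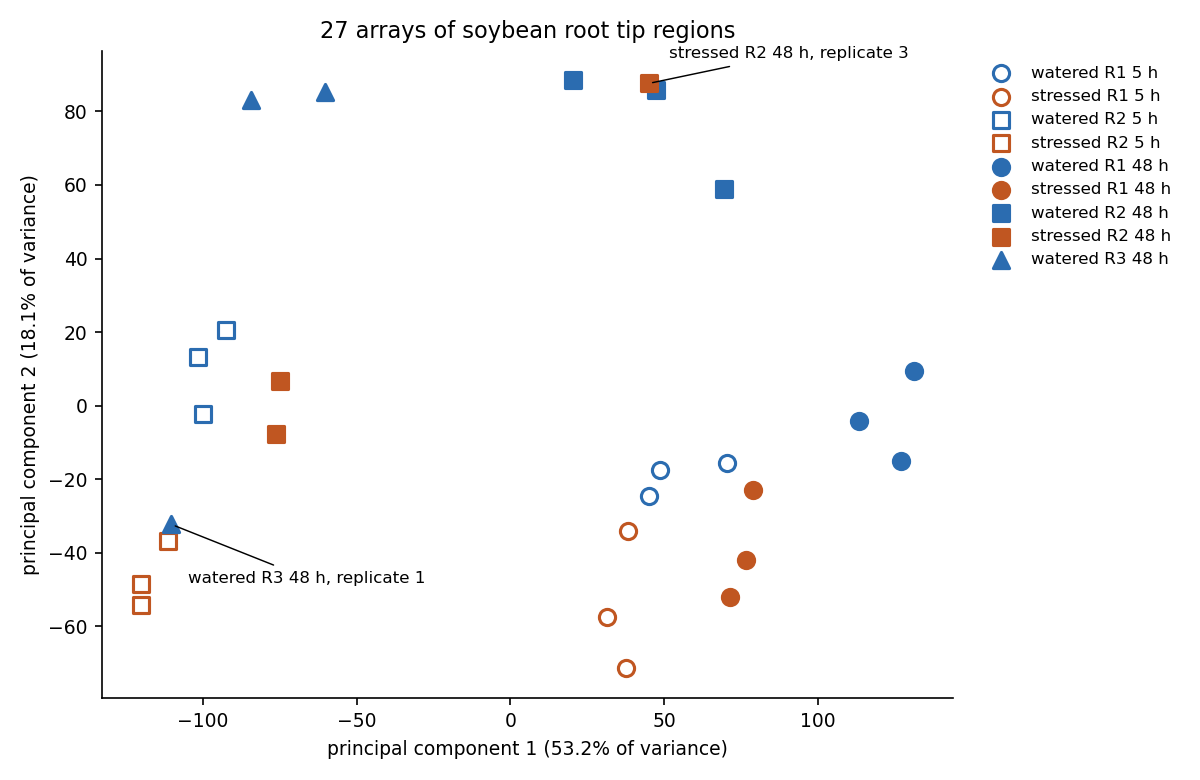
Principal components of the log2 intensities of the 27 arrays; each point is an array, the colour gives the treatment (watered or stressed), the shape the region (R1 to R3), and open points are 5 h. Component 1 holds 53.2% of the variance and component 2 holds 18.1%, and the 2 named arrays lie apart from the groups they are labelled with.

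The first comparison asked which genes responded to water stress in region 1 after 5 h. Genes of seed maturation were among the largest rises. The seed maturation protein gene PM30 rose by a log2 difference of 5.51 (3 arrays per group; adjusted p = 0.0278), from a mean log2 intensity of 5.94 ± 0.06 to 11.45 ± 0.35 (SD). That p value rests on a spread shared by all groups, the 2 arrays lying apart included, and not on these SDs. The well-watered mean lies at the background level, with 2 of 3 arrays just above it, so the size of this rise is uncertain. GOLS, which encodes galactinol synthase of the raffinose sugar pathway, rose by 2.42 ± 0.52 (SE), and the glutathione S-transferase gene GSTU1 rose by 2.96 ± 0.42. MFT rose at least 4.45-fold, since all 3 well-watered arrays lay below background. The ferritin genes SFERH-4 and H-1, which encode iron storage proteins, rose by 0.92 ± 0.12 and 0.65 ± 0.12. On the other side, the receptor kinase gene SARK fell by 4.02 on the log2 scale and NIR, encoding nitrite reductase, fell by 2.91. PHT1-3, a phosphate transporter gene, fell at least 2.53-fold, and the aquaporin gene PIP2-4, whose product is a water channel, fell by 0.68.

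Of 23 tested genes of late embryogenesis abundant (LEA) and seed maturation proteins, 3 rose, 0 fell and 20 were not called (camera adjusted p = 1.33e-10; adjusted p = 0.18 with an estimated correlation), and in the 25 arrays 11 rose and 0 fell (camera adjusted p = 1.84e-15; adjusted p = 0.0388 with an estimated correlation). Of 32 glutathione S-transferase genes 1 rose and 31 were not called (camera adjusted p = 0.000818; adjusted p = 0.481 with an estimated correlation), and leaving out water-stressed replicate 2 ended that list call (camera adjusted p = 0.078). Of 6 ferritin and iron transport genes 2 rose and 4 were not called (camera adjusted p = 0.000818; adjusted p = 0.18 with an estimated correlation). Of 41 WRKY transcription factor genes 2 fell and 39 were not called, and 4 fell adjusted over the list alone (camera adjusted p = 0.00438; adjusted p = 0.481 with an estimated correlation). WRKY58 fell by 1.03 and WRKY33 fell by 0.81, and median centring of the arrays ended the WRKY33 call. Over all tested probe sets 536 were called, 253 higher and 283 lower, and 2382 in the 25 arrays, 1320 higher and 1062 lower, although neither omitted array belongs to these groups. The differences are the same in both fits, so the added calls come from the estimate of the shared spread. Which direction held more calls also turned with quantile normalization (277 higher and 267 lower) and with median centring (308 and 244). Leaving out well-watered replicates 1, 2 and 3 gave 295, 257 and 328, and leaving out water-stressed replicate 3 gave 317.

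In region 2 after 5 h of stress, seed maturation genes again stood among the largest rises. PM30 rose at least 50.2-fold and PM29 at least 13.6-fold, each from well-watered arrays that all lay below background. The seed maturation genes PM16 and PM41 rose by 4.46 ± 1.31 and 4.36 ± 0.87. LOX3, a lipoxygenase gene, rose by 3.77 ± 0.86, GOLS by 2.92 ± 0.52 and the transcription factor genes BZIP71, HSF-08 and NAC4 by 3.24 ± 0.47, 3.05 ± 0.68 and 2.76 ± 0.57. EXP2 and EXP1, which encode expansins that loosen cell walls, rose by 2.26 ± 0.22 and 1.80 ± 0.38. Log2 differences were negative for NIR (-4.36 ± 0.53), GASA6 (-2.84 ± 0.75), IQD18 (-2.60 ± 0.30) and WRKY57 (-1.79 ± 0.26).

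Of the 23 LEA and seed maturation genes 11 rose and 12 were not called (camera adjusted p = 3.59e-11; adjusted p = 0.198 with an estimated correlation), and in the 25 arrays 17 rose and 1 fell (camera adjusted p = 3.34e-15; adjusted p = 0.0413 with an estimated correlation). Of 11 genes of osmolyte metabolism 3 rose, GOLS and MIPS4 (1.22 ± 0.25) among them, and 8 were not called (camera adjusted p = 0.00333; adjusted p = 0.146 with an estimated correlation). Of 41 WRKY genes 7 fell and 34 were not called, with 9 falling adjusted over the list alone (camera adjusted p = 0.00333; adjusted p = 0.53 with an estimated correlation). Of 17 aquaporin genes 3 fell and 14 were not called, and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.0115; adjusted p = 0.611 with an estimated correlation). PIP2-2 fell by 1.36 and PIP2-4 fell by 0.40, although another probe set of PIP2-4 had the opposite sign and median centring of the arrays ended the PIP2-4 call. Of 6 heat shock protein and chaperone genes 2 fell and 4 were not called, and 4 fell adjusted over the list alone (camera adjusted p = 0.0115; adjusted p = 0.263 with an estimated correlation). That call rests on 1 array, since without well-watered replicate 2 the list mean went from -0.675 to -0.089 (camera adjusted p = 0.171). Over all probe sets 2915 were called, 1508 higher and 1407 lower, and 6061 in the 25 arrays. Leaving out well-watered replicates 1, 2 and 3 gave 1391, 1577 and 1786, and leaving out water-stressed replicates 1 and 3 gave 1460 and 1546.

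After 48 h of stress in region 1, SALI5-4A rose at least 32.4-fold and ACS1 at least 2.57-fold, both from well-watered arrays that all lay below background. PRP2, encoding a proline-rich wall protein, rose by 4.57 ± 1.06 and AS2, encoding asparagine synthetase, by 3.34 ± 0.66. The GASA genes GASA24 and GASA29 rose by 1.92 ± 0.20 and 1.72 ± 0.23, and the sieve element gene SEOC rose by 2.17 ± 0.26. GSTU37 fell by 3.54, NIR fell by 2.80, CDPK fell by 1.48 and GA20OX3, a gibberellin synthesis gene, fell by 1.44. The ferritin gene SFERH-4 rose by 1.03 ± 0.12 and PIP2-4 by 1.04 ± 0.11.

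Of 17 aquaporin genes 6 rose and 11 were not called, and 9 rose adjusted over the list alone (camera adjusted p = 4.44e-06; adjusted p = 0.555 with an estimated correlation). Of 15 genes on the gibberellin list 4 rose and 11 were not called, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.0222; adjusted p = 0.555 with an estimated correlation). GASA24 and GASA29 are members of it, and in the 25 arrays the camera adjusted p was 0.0746. Of 18 NAC transcription factor genes 1 rose and 17 were not called, and 3 rose adjusted over the list alone (camera adjusted p = 0.00066; adjusted p = 0.555 with an estimated correlation). Of 23 LEA and seed maturation genes 1 rose, PM34 at least 3.69-fold, and 22 were not called (camera adjusted p = 0.00066; adjusted p = 0.555 with an estimated correlation), and 7 rose in the 25 arrays (camera adjusted p = 5.77e-06; adjusted p = 0.207 with an estimated correlation). In all 795 probe sets were called, 475 higher and 320 lower, and 3537 in the 25 arrays. With the background level added before the logarithm 365 were higher and 378 lower. Leaving out well-watered replicates 2 and 3 gave 283 and 369, and leaving out water-stressed replicates 2 and 3 gave 293 and 345.

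**Figure D2:**
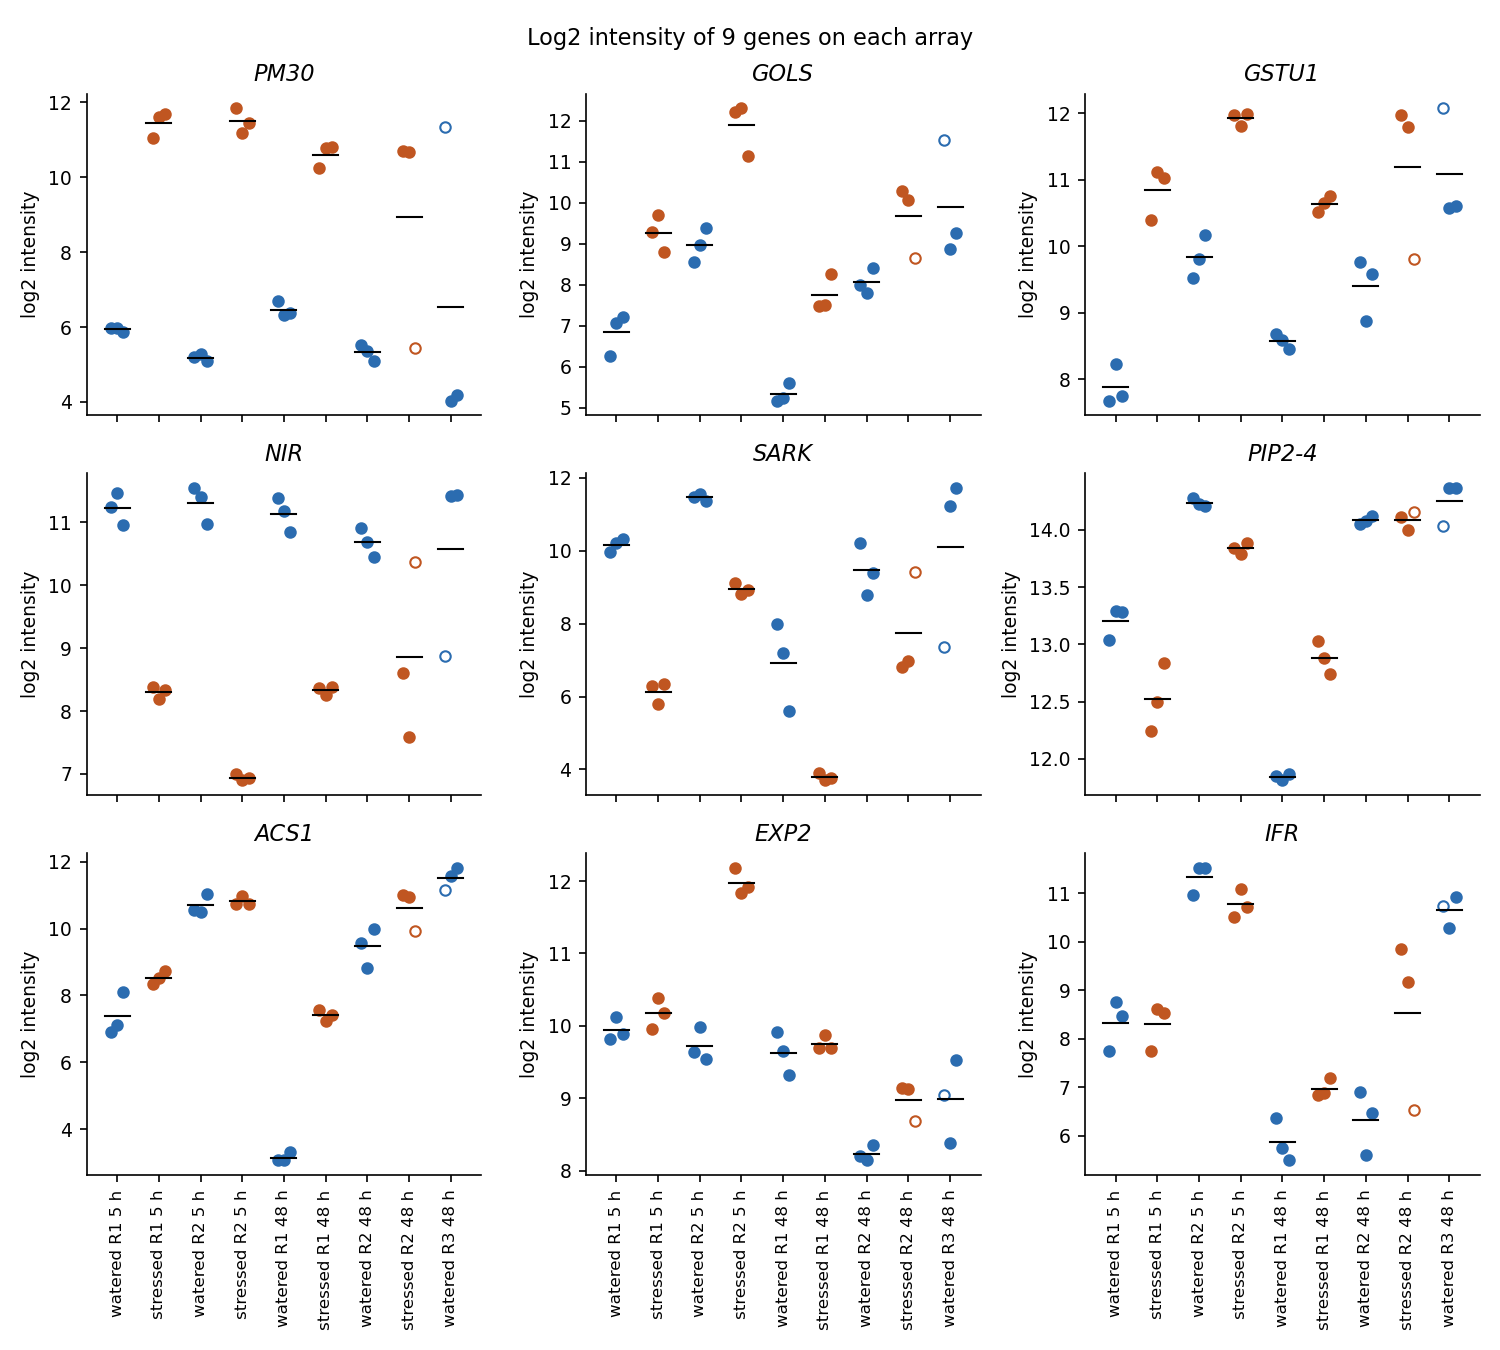
Log2 intensity of 9 genes on each of the 27 arrays, by group (R1 to R3, regions); points are arrays, black lines are group means, colour gives the treatment, and open points are the 2 arrays that lie apart from their groups. PM30 stands above a log2 intensity of 10 on 11 of the 12 water-stressed arrays and on the array labelled well-watered region 3, replicate 1 (11.34).

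Region 2 after 48 h holds the water-stressed array that lies among the well-watered ones, and the count rose from 1490 to 9026 without it. With all 27 arrays CYP93A1, a gene on the flavonoid and isoflavonoid list, rose by 3.35 ± 0.91, the lipoxygenase gene LOX9 by 3.35 ± 0.93, GASA13 by 1.90 ± 0.51, GSTU1 by 1.79 ± 0.42 and DREB1 by 1.60 ± 0.46. PDH fell by 1.54, GASA21 fell by 1.84 and BZIP48 fell by 1.82. The spread among the 3 stressed arrays was wide, at an SD of 2.61 for CYP93A1 against 0.18 in the well-watered group. In the 25 arrays, with 2 stressed arrays, SALI5-4A rose by 6.70 ± 0.75. PM16 and PM30 rose at least 36.3-fold and 24.1-fold there, XET1, encoding an enzyme that remodels wall xyloglucan, at least 30.2-fold and PRP2 by 5.84 ± 0.35, while GASA33 fell by 3.03, GASA6 fell by 2.76, NIR fell by 2.58 and SARK fell by 2.56. Of these 9 genes PM30, XET1, GASA33, GASA6, NIR and SARK were not called with 27 arrays.

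Of 23 genes of flavonoid and isoflavonoid synthesis 5 rose and 18 were not called with 27 arrays (camera adjusted p = 2.98e-06; adjusted p = 0.307 with an estimated correlation). In the 25 arrays 16 rose and 1 fell (camera adjusted p = 1.07e-07; adjusted p = 0.0166 with an estimated correlation). Of 32 glutathione S-transferase genes 5 rose and 27 were not called with 27 arrays (camera adjusted p = 1.18e-06; adjusted p = 0.307 with an estimated correlation). In the 25 arrays 20 rose and 1 fell (camera adjusted p = 8.72e-08; adjusted p = 0.122 with an estimated correlation). Of 18 NAC genes 4 rose and 14 were not called with 27 arrays, and 11 rose adjusted over the list alone (camera adjusted p = 5.94e-06; adjusted p = 0.307 with an estimated correlation). In the 25 arrays 13 rose (camera adjusted p = 5.9e-07; adjusted p = 0.122 with an estimated correlation). Of 23 LEA and seed maturation genes 2 rose and 21 were not called with 27 arrays (camera adjusted p = 2.83e-05; adjusted p = 0.393 with an estimated correlation), and 15 rose in the 25 arrays (camera adjusted p = 2.62e-07; adjusted p = 0.122 with an estimated correlation). Of 8 sieve element occlusion genes 0 rose and 8 were not called with 27 arrays (camera adjusted p = 0.00134; adjusted p = 0.393 with an estimated correlation), and in the 25 arrays 6 rose and 0 fell, with a median of 1.31 (camera adjusted p = 0.000719; adjusted p = 0.36 with an estimated correlation).

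Over all probe sets 1490 were called with 27 arrays, 979 higher and 511 lower. In the 25 arrays 10685 were called, 5528 higher and 5157 lower, of which 1486 were among the 1490. Leaving out water-stressed replicate 3 alone gave 9026. Leaving out water-stressed replicate 1 or 2 or well-watered replicate 1, 2 or 3 gave 0 by limma; 7731 probe sets had an unadjusted p under 0.05 with all arrays.

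**Figure D3:**
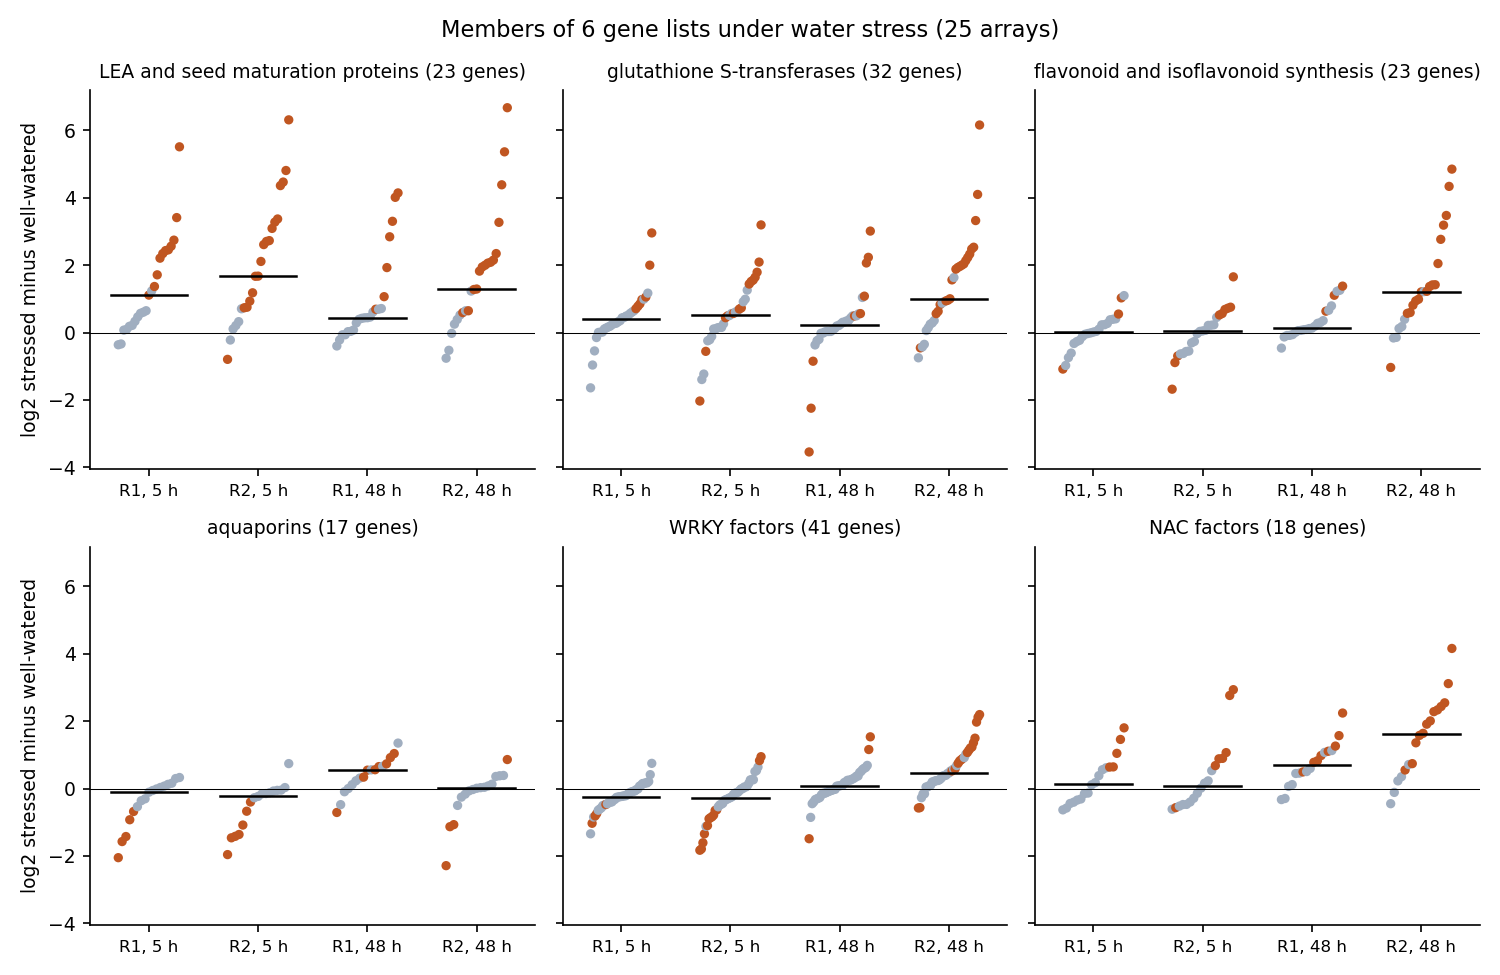
Log2 difference, water-stressed minus well-watered, of the members of 6 gene lists in regions 1 and 2 (R1, R2) at 5 h and 48 h, from the 25 arrays; each point is a gene, orange points have adjusted p under 0.05, and black lines are list medians. The median of the 23 flavonoid and isoflavonoid genes in region 2 at 48 h is 1.21.

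Water-stressed region 2 was also compared with well-watered region 3 at 48 h. With 27 arrays the auxin carrier gene PIN2A was higher in stressed region 2 by 2.30 ± 0.39, EXP1 by 1.97 ± 0.38, the fatty acid desaturase gene FAD3C by 1.96 ± 0.24 and GASA32 by 1.46 ± 0.23. HO3 was lower by a log2 difference of -2.58 ± 0.56, CYP93A3 by -2.45 ± 0.45 and IFR by -2.13 ± 0.54, and the call of IFR ended in the 25 arrays. In those arrays PM30 was at least 26.7-fold higher, LOX3 higher by 4.69 ± 0.25 and LEA5 by 3.96 ± 0.31, while SARK was lower by a log2 difference of -4.57 ± 0.48, NIR by -3.33 ± 0.25 and PIP2-8 by -3.31 ± 0.31. None of these 6 was called with 27 arrays, where the log2 differences were 2.42 for PM30, 2.02 for LOX3, 1.09 for LEA5, -2.36 for SARK, -1.72 for NIR and -0.61 for PIP2-8. In the 25 arrays 1 of the 2 other probe sets of PM30 had the same sign but was not called.

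Of the 23 flavonoid and isoflavonoid genes 4 were lower and 19 not called with 27 arrays (camera adjusted p = 0.0113; adjusted p = 0.761 with an estimated correlation). The 25 arrays gave the opposite direction and no call, with 5 higher, 0 lower and a median of 0.11 (camera adjusted p = 0.275; adjusted p = 0.679 with an estimated correlation). Of 41 WRKY genes 2 were lower and 39 not called, and 7 were lower adjusted over the list alone (camera adjusted p = 5.32e-05; adjusted p = 0.508 with an estimated correlation), and this call too was lost in the 25 arrays, with 7 lower (camera adjusted p = 0.145; adjusted p = 0.679 with an estimated correlation). The list of 23 LEA and seed maturation genes was not called with 27 arrays, with 1 gene higher and 22 not called (camera adjusted p = 0.12; adjusted p = 0.767 with an estimated correlation), and in the 25 arrays 14 were higher (camera adjusted p = 4.4e-11; adjusted p = 0.0765 with an estimated correlation). There 5 of 6 ferritin and iron transport genes were higher (camera adjusted p = 3.07e-06; adjusted p = 0.00268 with an estimated correlation), and 6 of 17 aquaporin genes were lower (camera adjusted p = 7.37e-07; adjusted p = 0.0765 with an estimated correlation). With 27 arrays 0 genes of either list were called (camera adjusted p = 0.0486 for both; adjusted p = 0.692 and 0.767 with an estimated correlation). Quantile normalization, median centring, no intensity trend and the replicate block each ended both list calls. The whole comparison called 828 probe sets, 338 higher and 490 lower, against 4149 in the 25 arrays, 2298 higher and 1851 lower, with 578 called in both in one direction. Leaving out well-watered region 3 replicates 1, 2 and 3 gave 2238, 371 and 333, and leaving out water-stressed replicates 1, 2 and 3 gave 1273, 1644 and 414.

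The regions were compared within each treatment and time. In well-watered roots at 5 h region 2 exceeded region 1 in SALI5-4A (4.43 ± 1.18), the germin-like gene GER16 (4.24 ± 0.99), GASA24 (2.90 ± 0.20) and 4CL1 of the phenylpropanoid pathway (3.33 ± 0.40). Region 1 exceeded region 2 in the protease inhibitor gene BBI-2 (-5.36 ± 1.11), WRI1B (-3.85 ± 0.42), the glutamine synthetase gene GS1alpha (-3.09 ± 0.24), PIN2A (-3.02 ± 0.39) and the DNA polymerase gene POLD1 (-1.24 ± 0.23). Of 17 aquaporin genes 12 were higher in region 2 and 5 not called, with 14 higher adjusted over the list alone (camera adjusted p = 6.21e-06; adjusted p = 0.375 with an estimated correlation). Of 41 WRKY genes 23 were higher, 2 lower and 16 not called, and adjusted over the list alone 23 were higher and 2 lower (camera adjusted p = 9.41e-07; adjusted p = 0.375 with an estimated correlation). Of 8 sieve element occlusion genes of the phloem 7 were higher and 1 not called (camera adjusted p = 2.23e-05; adjusted p = 0.375 with an estimated correlation). Between these regions 13556 probe sets were called, 6121 higher in region 2 and 7435 lower, and 15902 in the 25 arrays.

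In well-watered roots at 48 h ACS1 was at least 10.6-fold higher in region 2 than in region 1, GASA24 higher by 5.07 ± 0.20, GASA29 by 4.92 ± 0.23 and SEOC by 4.64 ± 0.26. PIN2A was lower by a log2 difference of -2.79 ± 0.39 and the chalcone synthase gene CHS8 by -2.75 ± 0.45. Of 17 aquaporin genes 15 were higher and 2 not called, with 15 higher adjusted over the list alone (camera adjusted p = 1.6e-12; adjusted p = 0.191 with an estimated correlation). Of 23 flavonoid and isoflavonoid genes 1 was higher, 10 lower and 12 not called (camera adjusted p = 0.0181; adjusted p = 0.703 with an estimated correlation). The count of called probe sets was 9812, 4173 higher and 5639 lower, and 12486 in the 25 arrays. Leaving out well-watered region 2 replicate 1 gave 6052.

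In region 3 against region 2 of well-watered roots at 48 h, IFR was higher in region 3 by 4.33 ± 0.54, PTS-L5 by 5.84 ± 0.79 and GER16 at least 16.5-fold. BZIP48 was lower by a log2 difference of -2.95 ± 0.43, WRI1B by -2.91 ± 0.42 and GASA33 by -2.90 ± 0.62. These values use the region 3 array that lies apart from its group. In the 25 arrays PTS-L5 was higher by 5.65 ± 0.46 and IFR by 4.28 ± 0.38, although another probe set of IFR was not called. BZIP48 was lower there by a log2 difference of -2.57 ± 0.25 and WRI1B by -2.66 ± 0.26. The largest fall there was that of BBI-2, at least 9.52-fold, which was not called with 27 arrays (adjusted p = 0.053). GER16 and GASA33 were not among the 5 largest rises or falls. With 27 arrays 14 of 23 flavonoid and isoflavonoid genes were higher in region 3, 1 lower and 8 not called (camera adjusted p = 3.86e-06; adjusted p = 0.329 with an estimated correlation). Of 18 NAC genes 11 were higher and 7 not called, with 11 adjusted over the list alone (camera adjusted p = 5.16e-05; adjusted p = 0.376 with an estimated correlation). For region 3 against region 2, 9628 probe sets were called, 5088 higher and 4540 lower, and 9331 in the 25 arrays, 7927 of them shared. Quantile normalization gave 4690 higher and 5593 lower and median centring 4432 and 5944, so the direction with more calls depends on the scaling.

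In stressed roots region 2 exceeded region 1 at 5 h in PC7 (5.24 ± 1.12), XET1 (4.74 ± 1.33), HO3 (4.68 ± 0.56) and EXP2 (1.80 ± 0.22), and was lower in ASP1 (-3.77 ± 0.84) and the desaturase gene SACPD-C (-3.29 ± 0.53). Of 44 MYB genes 22 were higher, 4 lower and 18 not called, and adjusted over the list alone 23 were higher and 5 lower (camera adjusted p = 0.000272; adjusted p = 0.361 with an estimated correlation). In the stressed roots of 5 h, 13367 probe sets were called, 6266 higher and 7101 lower, and 15743 in the 25 arrays. At 48 h GASA24 was higher in stressed region 2 by 3.59 ± 0.20, GASA29 by 3.50 ± 0.23 and ACS1 by 3.21 ± 0.31, while FAD2-1A was lower by a log2 difference of -2.68 ± 0.30 and PIN2A by -2.59 ± 0.39. In the 25 arrays, with 2 arrays of region 2, the largest rises were others, among them XET1 (4.69 ± 0.75), PC7 (4.65 ± 0.93), PTS-L5 (4.60 ± 0.46) and GASA22 (4.19 ± 0.35). The error of PC7 rests on the spread of all groups, while its SD there was 2.02 in region 2 and 1.97 in region 1. The largest falls there were those of BBI-2 (-3.34 ± 0.79) and WRI1B (-3.23 ± 0.26). XET1 was not called with 27 arrays (2.39). Of 17 aquaporin genes 13 were higher and 4 not called, and 13 were higher adjusted over the list alone (camera adjusted p = 1.93e-07; adjusted p = 0.407 with an estimated correlation). In those of 48 h, 10675 probe sets were called, 4998 higher and 5677 lower, and 13958 in the 25 arrays, 9743 of them shared.

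Well-watered roots also differed between the times. In region 1 the glutamine synthetase gene GS-2 was higher at 48 h by 2.11 ± 0.58 and the clock gene LHY by 1.13 ± 0.23, while GH was at least 21.6-fold lower and PRP2 lower by a log2 difference of -4.74 ± 1.06. Of 17 aquaporin genes 10 were lower and 7 not called, and 11 were lower adjusted over the list alone (camera adjusted p = 8.94e-14; adjusted p = 0.0687 with an estimated correlation). PIP2-4 was lower by a log2 difference of -1.36 ± 0.11. Between the times 2133 probe sets were called in region 1, 742 higher and 1391 lower, and 4890 in the 25 arrays. Leaving out 5 h replicates 2 and 3 gave 843 and 863, and leaving out 48 h replicates 2 and 3 gave 1160 and 811.

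In region 2 GS-2 was higher at 48 h by 3.42 ± 0.58, WRI1B by 3.10 ± 0.42 and GS1alpha by 2.33 ± 0.24. GSTU42 was at least 26.5-fold lower, G4DT, of the glyceollin branch of isoflavonoid synthesis, at least 22.6-fold lower and LOX7 lower by a log2 difference of -3.55 ± 0.35. Of 41 WRKY genes 26 were lower, 1 higher and 14 not called, and adjusted over the list alone 29 were lower and 1 higher (camera adjusted p = 9.95e-08; adjusted p = 0.397 with an estimated correlation). Of 23 flavonoid and isoflavonoid genes 14 were lower, 1 higher and 8 not called (camera adjusted p = 3.2e-05; adjusted p = 0.397 with an estimated correlation). In this region 12526 probe sets were called, 6747 higher and 5779 lower, and 14981 in the 25 arrays.

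**Figure D4:**
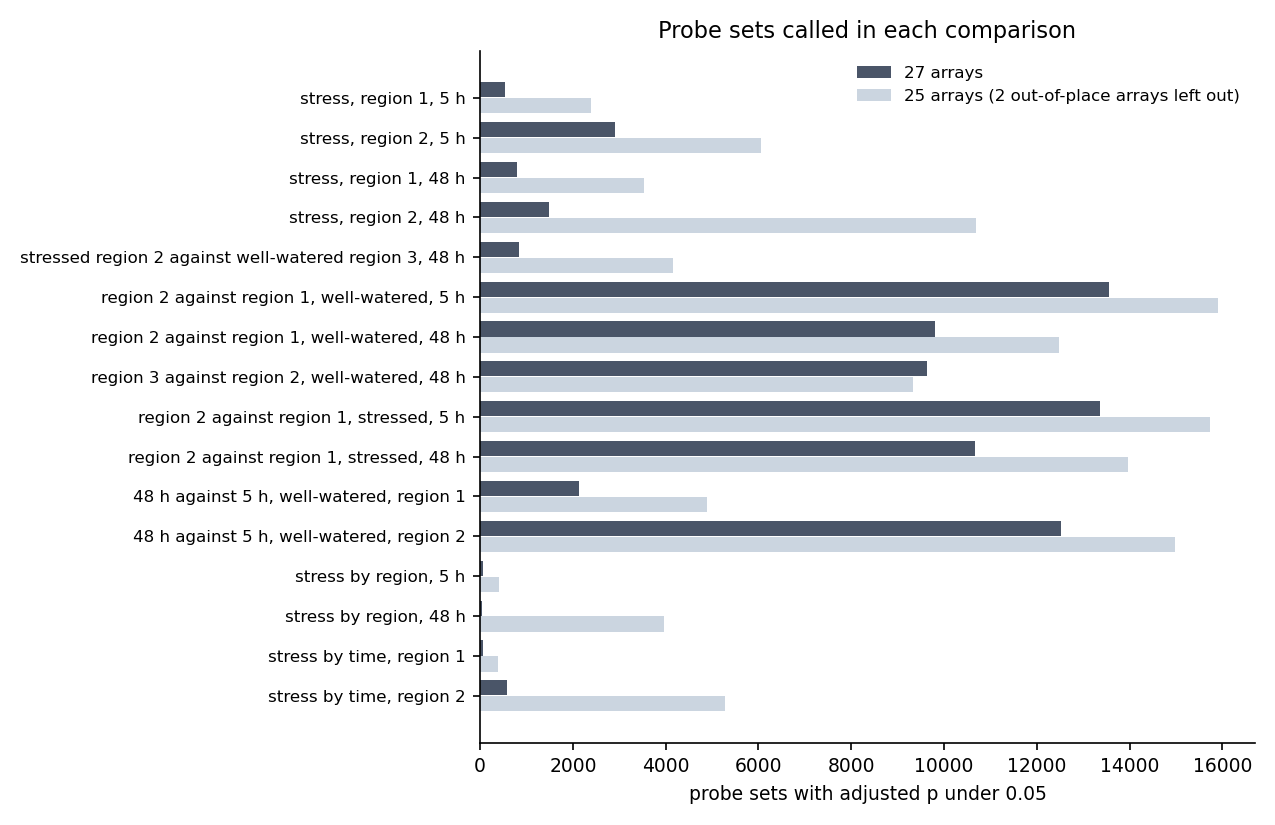
Number of probe sets with adjusted p under 0.05 in each of the 16 comparisons; dark bars are the 27 arrays and pale bars the 25 arrays. The pale bar is longer in all comparisons but that of region 3 with region 2, and for stress in region 2 at 48 h it stands at 10685 against 1490.

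The last comparisons tested whether the stress response itself differed between regions or times. The genes named here have no group below background on all of its arrays. At 5 h EXP2 responded more in region 2 than in region 1 by 2.03 ± 0.31 (adjusted p = 0.00188). At 48 h the response of GASA24 was smaller in region 2 by a log2 difference of -1.48 ± 0.28 and that of PIP2-4 by -1.03 ± 0.16, and that of LBD23 was more positive by 1.62 ± 0.25. In region 1 the response of PIP2-4 was more positive at 48 h than at 5 h by 1.72 ± 0.16 (adjusted p = 1.17e-05), as were those of GASA29 (2.46 ± 0.32) and NOD33 (2.33 ± 0.43). In region 2 the responses of IQD18 (2.92 ± 0.43) and HIR3 (2.47 ± 0.61) were more positive at 48 h, and those of GS1alpha (-1.86 ± 0.34) and EXP2 (-1.51 ± 0.31) more negative.

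For the stress response in region 1, 2 of 17 aquaporin genes were more positive at 48 h than at 5 h and 15 were not called, with 8 more positive adjusted over the list alone (camera adjusted p = 4.27e-10; adjusted p = 0.229 with an estimated correlation). In region 2, 5 of 41 WRKY genes were more positive at 48 h and 36 not called, with 6 adjusted over the list alone (camera adjusted p = 1.66e-09; adjusted p = 0.305 with an estimated correlation). The counts were 63 probe sets between regions at 5 h, 33 between regions at 48 h, 65 between times in region 1 and 573 between times in region 2, and 402, 3960, 382 and 5282 in the 25 arrays. Leaving out single arrays gave 40 to 55, 15 to 1811, 32 to 268 and 306 to 3640. For the regions at 5 h, leaving out replicate 2 of region 1 gave 40 (well-watered) and 41 (water-stressed). For the regions at 48 h it gave 15 and 21 without well-watered region 2 replicates 1 and 3, 21 without well-watered region 1 replicate 2, 19 and 21 without water-stressed region 1 replicates 2 and 3, and 1811 without water-stressed region 2 replicate 3. For the times in region 1 the count was 35 and 43 without well-watered 5 h replicates 2 and 3, 32 and 38 without well-watered 48 h replicates 2 and 3, 37 and 35 without water-stressed 48 h replicates 2 and 3, and 268 and 42 without water-stressed 5 h replicates 1 and 3. For the times in region 2 it was 345, 323 and 380 without well-watered 5 h replicates 1, 2 and 3, 306 and 310 without well-watered 48 h replicates 2 and 3, 320 and 321 without water-stressed 5 h replicates 1 and 3, and 364, 333 and 3640 without water-stressed 48 h replicates 1, 2 and 3. Separation of groups cannot be asked of these terms. Across tested probe sets, which are not independent replicates, the stress differences of both regions correlated with r = 0.754 at 5 h and 0.571 at 48 h, and those of both times with r = 0.426 in region 1 and 0.404 in region 2.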

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

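The tests of the 2 arrays that lie apart from their groups were chosen after their position had been seen, and so were the fit on 25 arrays, the splits that follow replicate numbers and the raising of values to the background level. The tests of the other patterns and the other splits were written down before their results were seen, although each pattern had been noticed in the same data.

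The stress effect differed between regions or times by a test of the difference itself, which called 63 probe sets between regions at 5 h, 33 between regions at 48 h, 65 between times in region 1 and 573 between times in region 2. Between regions at 5 h the difference was 2.031 for EXP2. Between regions at 48 h it was -3.105 for ACS1, -2.071 for MFT, -1.878 for PM34, 1.622 for LBD23, -1.482 for GASA24 and -1.033 for PIP2-4. Between times in region 1 it was 3.123 for ACS1, 2.457 for GASA29, 2.329 for NOD33, -2.282 for PM3, 2.153 for SPX3 and 2.026 for PHT1-3. Between times in region 2 it was 3.464 for CYP93A3, 3.207 for WRKY60, 2.923 for IQD18, 2.468 for HIR3, 2.411 for WRKY57, -2.385 for PM3, -2.327 for PM12, -1.86 for MFT, -1.857 for GS1alpha and -1.51 for EXP2. The sizes between regions at 48 h and between times in region 2 also rest on the stressed array that lies among the well-watered ones. The terms given for ACS1, MFT, PM34, PM3, SPX3, PHT1-3, CYP93A3, WRKY60, WRKY57 and PM12 hold at least 1 group below background on all 3 arrays, so the sizes of these differences are not measured. With values raised to the background level, which also narrows the spread of such groups, ACS1 came to -0.201 between regions and 0.219 between times, PM34 to -0.987 and SPX3 to 0.537, none of them called, so a difference in response is not held for these 3 genes. The others kept their sign and call.

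For these terms the samples were regrouped within each stratum. Of 100 splits, 10 called at least the 63 probe sets between regions at 5 h (highest other 117) and 7 at least the 33 between regions at 48 h (highest other 1503), so chance is not excluded for these counts when each region is regrouped on its own. Regrouping the same replicate numbers in both regions leaves 10 splits, too few for a share under 0.05, with a highest other of 0 against the real 63 and 0 against the real 33. For the times 4 of 100 splits called at least the 65 of region 1 (highest other 929) and 4 at least the 573 of region 2 (highest other 1547), a share under 0.05 in both. Splits other than the real one mix stressed with well-watered arrays in at least 1 stratum, which also weakens the stress effect itself. Their counts therefore do not test a difference between effects on its own. Each time was also regrouped on its own, although replicate numbers paired well-watered region 2 between the times. Splits calling many times the real count point to a structure of the samples, whose cause was not tested.

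Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. For stress the real count and the highest other were 536 and 0 in region 1 at 5 h, 2915 and 1 in region 2 at 5 h, and 795 and 0 in region 1 at 48 h, with 1 split as large in each. In region 2 at 48 h 2 splits called at least the 1490, and the highest other called 4849. For stressed region 2 against well-watered region 3, 2 splits called at least the 828, and the highest other called 6583. Both of these larger splits exchange one array between the groups and point to the structure weighed next. Between regions the pairs were 13556 and 0 (well-watered, 5 h), 9812 and 0 (well-watered, 48 h), 9628 and 950 (region 3 against region 2), 13367 and 89 (stressed, 5 h) and 10675 and 903 (stressed, 48 h). Between times they were 2133 and 0 in region 1 and 12526 and 1 in region 2, with 1 split as large in each of these 7. Where replicate numbers pair the arrays, 4 splits part every pair, again too few for a share under 0.05, and the highest other was 0 against the real 9812 (well-watered regions, 48 h), 13367 (stressed regions, 5 h) and 12526 (times, region 2).

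At 48 h 2 arrays lie away from the groups they are labelled with. On a score running from 0 for well-watered to 1 for the other water-stressed region 2 arrays, the array labelled water-stressed region 2, replicate 3, scored 0.07, inside the -0.22 to 0.10 of the well-watered arrays, which is consistent with a wrong label on a well-watered sample. On a score from 0 for the other well-watered region 3 arrays to 1 for water-stressed region 2, the array labelled well-watered region 3, replicate 1, scored 0.81. The other region 3 arrays scored -0.09 to 0.08. This would follow from a wrong label on a stressed sample, but the test asked only for a score nearer the stressed end. That rule is looser than the one for the first array. Both scores use 168 probe sets called in one direction by stress in region 1 at 48 h and region 2 at 5 h. A swap between stressed and well-watered region 2 is argued against, since 0 arrays labelled well-watered region 2 lay nearer to stressed replicates 1 and 2 than to the rest of their own group, and for the first array 0 of 2 measures of signal and background lay outside the range of the others, although its background level of 71.0 was the highest of all arrays and its soybean median (201) and upper quartile (344.6) the lowest, so a weaker hybridisation of it is not excluded. These levels lie near those of the well-watered region 2 arrays of 48 h, with backgrounds of 68.4, 68.1 and 69.3 and soybean medians of 207, 222 and 208. For the second array 2 of 2 measures lay outside the range of the others, but toward a cleaner signal (77.2% of soybean probe sets above background, the highest, and a median of 16.4 for the other species, the lowest), while the test as written named no direction, so a hybridisation unlike the others stays open.

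Well-watered region 2 differed between 48 h and 5 h at 12526 probe sets and region 1 at 2133. A difference in array processing between the times would move both regions alike, and the root mean square difference was 0.601 in region 1 against 1.03 in region 2, a ratio of 0.58, which argues against it as the whole cause. The region 2 minus region 1 difference at 5 h correlated across probe sets, which are not independent, with region 3 minus region 1 at 48 h (0.897) by 0.26 more than with region 2 minus region 1 at 48 h (0.639). The first value leaves out the array labelled well-watered region 3, replicate 1, and with that array it was 0.924. Region 2 may therefore lie at another stage of the root axis at the 2 times, through growth or through where the sections were taken. Only the times of well-watered roots were compared, and days of harvest are not given, so a batch acting on region 2 alone stays open.

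Water-stressed region 2 at 48 h resembled well-watered region 3, and without the 2 arrays 4149 probe sets were called between them against 10685 for stress in region 2, so those arrays do not account for the likeness. The stressed region 2 minus region 1 difference correlated with well-watered region 3 minus region 1 (0.875) by 0.21 more than with region 2 minus region 1 (0.666) without the 2 arrays, which is consistent with stressed region 2 lying at the stage of region 3. With all arrays the values were 0.854 and 0.765, a margin below the 0.1 set for the test, so this result depends on leaving those arrays out. The stress effect in region 2 correlated at 0.723 with region 3 minus region 2, and at 0.591 to 0.694 with split controls. In 20 simulations of noise alone a shared control group gave 0.397. That value is set by the group sizes and the simulations held no real effect, so it is no benchmark for the correlation seen. Stress acting on the same genes without a change of stage stays open, as does a shift of the cutting position with root length.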

How the results depend on the processing

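Leaving out the 2 arrays that lie apart from their groups, the replicate block within treatment and time and the raising of values to the background level were chosen after the data were seen, and so was the way array weights were estimated. The estimate first planned did not converge (largest weight 67.5) and was replaced, after its counts had been seen, by one made gene by gene, with 0.111 and 0.123 for the 2 arrays.

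In stressed region 2 against well-watered region 3, 3 lists changed direction, none of them called after the change. The mean of the flavonoid and isoflavonoid list went from -0.355 to 0.195 with array weights and 0.315 in the 25 arrays, that of the sieve element occlusion list from -0.592 to 0.065 and 0.041, and that of the general phenylpropanoid list from -0.702 to 0.123 in the 25 arrays. Named genes changed sign in 15 values, 0 of them called under either fit. The direction with more calls turned in 33 alternative counts from 11 comparisons. Of 636 results for named genes under each alternative, 9118 values kept their side of the threshold, 245 passed it and 1034 no longer did, 766 of these with an array left out. Of 128 called list tests 0 kept the call with an estimated correlation (smallest adjusted p 0.0687), and over all alternatives 2084 values kept it, 311 did not and 5 changed the direction given by the list test. All 16 counts stayed within 1.5 times under quantile normalization, median centring, no intensity trend and the replicate block. With the replicate block stress called 592 in region 1 and 3093 in region 2 at 5 h, and 840 and 1583 at 48 h. In the 3 comparisons whose numbers pair the arrays the block gave 10116 (well-watered regions, 48 h), 13746 (stressed regions, 5 h) and 12961 (times, region 2), ended the call of the nitrogen list in the first (adjusted p 0.0558) and changed no other call of a list or named gene there. With values raised to the background level the differences between stress effects called 194 and 35 between regions at 5 h and 48 h and 76 and 741 between times, of which 54, 23, 52 and 519 were called before. Scaling moved the median of all probe sets by at most 0.097 log2.

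Without the 2 arrays the counts were 2382 and 6061 for stress in regions 1 and 2 at 5 h, 3537 and 10685 at 48 h, 4149 for stressed region 2 against well-watered region 3, 4890 between times in region 1, and 402, 3960, 382 and 5282 for the differences between stress effects (regions at 5 h and 48 h, times in regions 1 and 2). Array weights gave, for the same results, 2090, 12411, 11513, 11894, 4062, 9006, 638, 6528, 4821 and 7641, and 20361 (region 2 against 1, well-watered, 5 h), 17226 (stressed, 48 h) and 19810 (times, region 2). An adjusted p under 0.01 gave 244, 1103, 292 and 0 for stress, 223 for stressed region 2 against region 3, 5988, 5562 and 6112 between regions at 48 h (well-watered 2 against 1, 3 against 2, stressed), 817 and 7863 between times, and 35, 16, 30 and 185 for the differences between stress effects. A fit on the compared groups alone gave 1344, 6430, 1898 and 0 for stress and 0 for stressed region 2 against region 3, each 0 by limma, against 7731 probe sets with an unadjusted p under 0.05 for stress in region 2 at 48 h with all groups. It gave 5067 for region 3 against 2, 4042 for stressed regions at 48 h, 6272 between times in region 1 and 313, 6, 210 and 266 for the differences. Between regions at 5 h the difference of stress effects called 133 with the background level added before the logarithm, 109 without a filter and 22 with the stricter one, and without a filter stress in region 2 at 48 h called 925. A fit on fewer arrays has fewer residual degrees of freedom, and a stricter threshold calls fewer by construction. Without the 2 arrays, comparisons that hold neither of them keep their differences. Their counts therefore changed through the estimate of the spread shared by all groups. A fit on the compared groups alone also keeps the differences and estimates the spread from those groups only. For the other changes the cause was not tested.

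With single arrays left out, the counts ran from 257 to 462 and 1391 to 2134 for stress in regions 1 and 2 at 5 h, 283 to 1169 and 0 to 9026 at 48 h, and 333 to 2238 for stressed region 2 against region 3. Between regions they ran from 10264 to 11873 and 6052 to 9759 in well-watered roots at 5 h and 48 h, 6776 to 10029 for region 3 against 2, and 10681 to 12720 and 7180 to 12489 in stressed roots. Between times they ran from 811 to 1869 and 9378 to 11756, and for the differences from 40 to 55, 15 to 1811, 32 to 268 and 306 to 3640. The correlations of stress effects moved beyond their spread in 2 of 8 settings, to 0.481 between regions at 48 h and 0.449 between times in region 2 with probe sets above background on all arrays. Signal over background limits genes near the floor, whose folds are given as lower bounds.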

Other observations

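All tests in the next paragraph rest on the 25 arrays, chosen after the data were seen.

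In region 2 at 48 h of stress 12 of 19 lipoxygenase and jasmonate genes rose (camera adjusted p = 2.48e-06; adjusted p = 0.0914 with an estimated correlation). Of 13 genes of defence and protease inhibitors 9 rose and 0 fell, with a median of 1.25 (camera adjusted p = 1e-05; adjusted p = 0.0436 with an estimated correlation). The stress effect on 23 flavonoid and isoflavonoid genes was more positive in region 2 than in region 1 at 48 h for 12 and more negative for 0 (camera adjusted p = 1.86e-07; adjusted p = 0.0192 with an estimated correlation). In region 2 it was more positive at 48 h than at 5 h for 13 of them and more negative for 1 (camera adjusted p = 1.2e-07; adjusted p = 0.0171 with an estimated correlation). The stress effect on 17 aquaporin genes in region 1 was more positive at 48 h for 6 and more negative for 0 (camera adjusted p = 4.86e-11; adjusted p = 0.0451 with an estimated correlation).

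With all 27 arrays, genes of nitrogen uptake and assimilation were lower in well-watered region 2 than in region 1 at 48 h. Of 13 genes 6 were lower, 0 higher and 7 not called, with a median log2 difference of -1.23 (camera adjusted p = 0.0426; adjusted p = 0.284 with an estimated correlation). With the replicate number as a block the camera adjusted p was 0.0558, so the list was not called, nor was it without replicate 1 of either region (0.0559 and 0.0507). Of 8 genes of DNA replication and cell division 2 fell and 6 were not called under stress in region 2 at 5 h (camera adjusted p = 0.013; adjusted p = 0.146 with an estimated correlation). Of 9 genes on a photosynthesis list, included as a sign of light or shoot material, 2 rose and 7 were not called in that comparison (camera adjusted p = 0.0115; adjusted p = 0.208 with an estimated correlation). The photosynthesis call ended without water-stressed replicate 1, where the list mean went from 0.685 to 0.389 (camera adjusted p = 0.118), and with the stricter filter (0.378; camera adjusted p = 0.133). Under stress in region 1 at 5 h the photosynthesis list was called with 0 of 9 genes called (camera adjusted p = 0.006; adjusted p = 0.18 with an estimated correlation), and the sieve element occlusion list with 0 of 8 (camera adjusted p = 0.00633; adjusted p = 0.481 with an estimated correlation). Leaving out water-stressed replicate 3 ended the latter call (camera adjusted p = 0.131). At 48 h 1 of 8 sieve element occlusion genes rose in region 1 (camera adjusted p = 0.0446; adjusted p = 0.64 with an estimated correlation), a list call that the background level added before the logarithm ended (camera adjusted p = 0.112). The replicate block, a fit on the compared groups alone and array weights ended it too (camera adjusted p = 0.0507, 0.0687 and 0.289). Whether other tissue entered the sections was not tested.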
